A study of Mus musculus with 2 samples.

How the data were processed

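Zfp217, a zinc finger protein found in CoREST and CtBP corepressor complexes, was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in CCE, a mouse embryonic stem cell line. The series holds 1 library from a Zfp217 immunoprecipitation and 1 input library of the same line, and neither was treated. Per the labels' protocols, CCE cells grew on gelatin without feeder cells in serum and leukemia inhibitory factor. Chromatin was fixed in 1% formaldehyde for 10 min, sheared by sonication and precipitated with 10 µg of a Zfp217 antibody. Fragments of 200 to 300 bp were cut from a 2% gel and amplified over 16 PCR cycles, per the labels' protocols.

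The authors deposited one peak list for the series, with 4 columns: chromosome, start, end and a peak name. The submitters' processing notes name CASAVA 1.4, Bowtie2, MACS2 and the build mm9, without giving their roles or settings. The peak-calling threshold, the handling of duplicate reads, and whether the input served as the control are not given in the sources used here. The list has no column of height, fold enrichment, score or probability. Read depth is therefore unknown, and no value could be given for the input library. Starts were counted from 0 in the deposited list and are printed here counted from 1. All coordinates are mm9.

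Because the list carries no score, width took the place of score wherever peaks were ranked or filtered. Peaks were ranked to name the 10 widest, and clusters of at least 3 peaks with gaps of at most 10 kb were ranked by peaks per kb to name the first 3. The chromosomes with the highest and lowest density were named as well. These rules and 1 set of alternatives were fixed before the data were examined. The clusters with most peaks, the 1 Mb bins with most peaks and the groups among the widest 1% of peaks were named after their values were seen. The comparison of X with the autosomes was planned with intervals only. Its binomial test, the widths on X, the correlation with gene density, the count of pairs within 500 bp, the empty bins and the tests on the widest 1% were also added after the data were examined. The widest 1% were linked into groups of at least 3 where no gap between them passed 1 Mb.

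Peak density was computed for chromosomes 1 to 19 and X as peaks per Mb, with the last peak end as the chromosome's length and an exact 95% Poisson interval. The X chromosome was compared with the autosomes by an exact binomial test, two-sided. The interval and the test take peaks as independent, so clustering of peaks makes the interval too narrow and p too small. Spacing and clustering were set against 100 random placements of the same peaks within the first and last peak of each chromosome, and p is one-sided in the direction observed, so that the smallest p they can give is 0.0099. Gaps in the assembly were not masked. Widths were compared by drawing 100000 random sets of as many peaks, two-sided. Correlations over chromosomes carry permutation p-values from 100000 permutations, two-sided, with Benjamini-Hochberg adjustment. Intervals of a median are from order statistics. Peaks, chromosomes and genes are not replicates, and every interval and p-value here describes the positions within this 1 list and covers counting or placement error only.

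No genome or annotation of mm9 was used, so peaks were not assigned to genes, promoters, exons or introns, and no sequence or motif was examined. A RefSeq gene table of the assembly GRCm38.p6 served only to count genes per chromosome and to see which genes neighbour each other; none of its positions was set against a peak. It held 21627 protein-coding genes on these 20 chromosomes. The 11 lists of named genes fixed beforehand, with 310 genes, needed positions and were not used here. The 4 gene families defined by symbol (histone, Hox cluster, zinc finger and olfactory receptor genes) were counted per chromosome; tRNA genes were added after the data were examined.

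The placement test was tested on simulated data with the real widths and chromosome spans of 18639 peaks. Without clustering it gave 1.07 times the clusters of random placement, and with 400 planted clusters the excess over random placement came to 95.0% of them. The data without clustering came from the same random placement, so a ratio near 1 was fixed by construction. Neither uneven density along a chromosome nor 1 region split into several peaks was simulated. The alternatives were the wider 50% and 25% of peaks, merging of peaks within 1000 bp, other cluster gaps, placement over the whole genome and distances between midpoints. Alternatives added after the data were examined were placement within 1 Mb bins, removal of the narrowest peaks, merging for the clusters, genes without olfactory receptors, and all those of the gene density correlation and the widest peaks. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.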

Results

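The binding of Zfp217 across the genome of CCE mouse embryonic stem cells was described by 18737 peaks from 1 immunoprecipitated library, called by the authors and spread over 31 chromosomes and contigs of mm9. Together the peaks covered 6.90 Mb, and none overlapped another. Chromosomes 1 to 19 and X held 18639 peaks, or 99.5%. Chromosome Y held 2 peaks, chromosome M held 1, and the unplaced contigs held 95. Read depth was unknown, no second immunoprecipitation was analysed here, and no value in the list could be set against the input library. The spread between replicates could therefore not be measured for any value.

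Most peaks were narrow. The median width was 321 bp (95% interval of the median 317 to 323), and the middle 50% of peaks lay between 227 and 467 bp. The narrowest width, 157 bp, was shared by 682 peaks, 10.1 times the mean of 67.7 peaks at each of the next 10 widths. At the other end, 195 peaks (1.04%) were wider than 1 kb and 17 were wider than 2 kb.

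**Figure D1:**
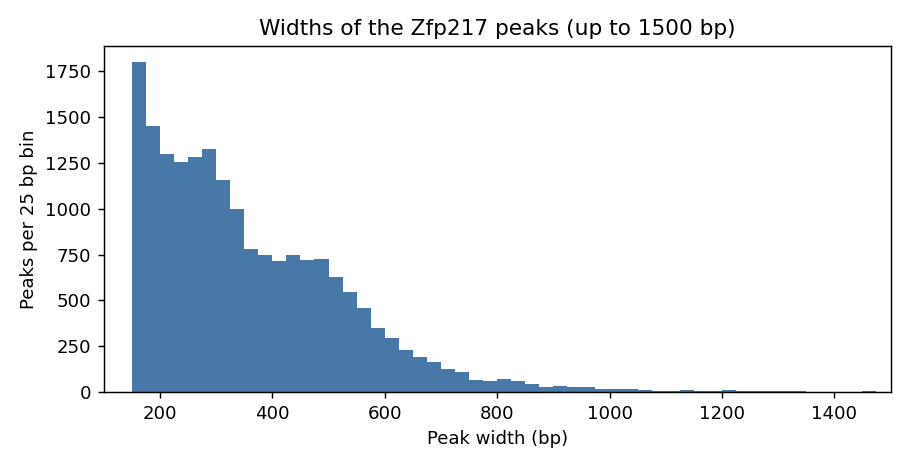
Histogram of peak width in bp (x axis) against the number of peaks per 25 bp bin (y axis) for the 1 Zfp217 peak list, drawn up to 1500 bp. The distribution starts at 157 bp, has its median at 321 bp and thins out above 1 kb.

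The first question the profile addresses is where in the genome Zfp217 peaks were found. Chromosome 11 had the highest density, with 12.3 peaks per Mb (95% Poisson interval 11.7 to 12.95, 1500 peaks). It was followed by chromosome 17 with 9.99 peaks per Mb, chromosome 19 with 9.82 and chromosome 7 with 9.43. The lowest autosomal density was on chromosome 1, with 4.81 peaks per Mb (4.51 to 5.13), and chromosome X was lower still, with 3.59 (3.31 to 3.89, 598 peaks). The intervals of chromosomes 11 and 1 lay far apart, so their difference exceeded the counting error of independent peaks.

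**Figure D2:**
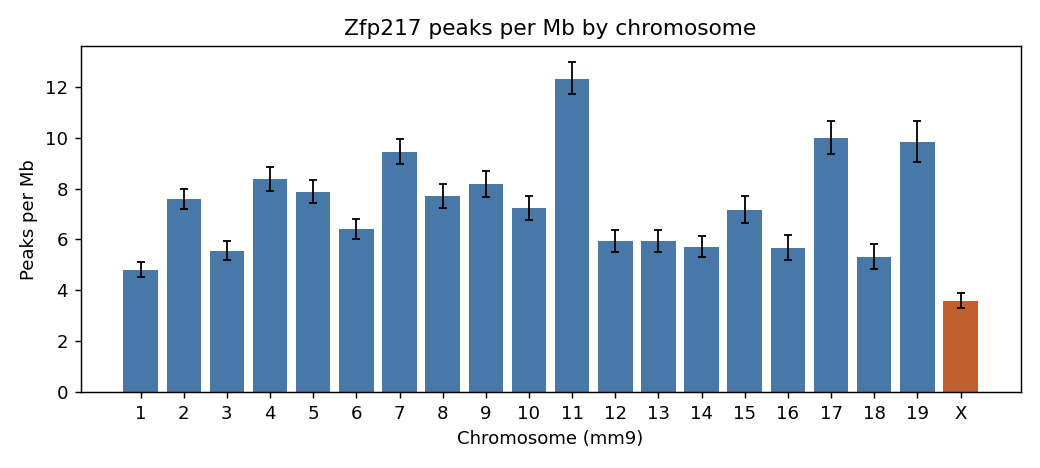
Peaks per Mb (y axis) on each mm9 chromosome (x axis), with bars from 0 and error bars for the exact 95% Poisson interval; autosomes are blue and X is orange. Chromosome 11 stands highest at 12.3 and X lowest at 3.59.

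Peak density followed gene density. Chromosomes 11, 17, 19 and 7 carried 13.2, 11.1, 11.5 and 13.3 protein-coding genes per Mb, whereas chromosomes 1, 18 and 12 carried 6.11, 5.62 and 5.62. Over the 20 chromosomes Pearson's r between the densities was 0.92 and Spearman's rho was 0.93. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 1e-05 over the 7 settings tried. Without chromosomes 7 and 11, which lie farthest from the median gene density, r was 0.92. The number of peaks per protein-coding gene ran from 0.708 on chromosome 7 to 1.06 on chromosome 12 among the autosomes. Chromosome 7 carries 237 of the 1106 olfactory receptor genes, a family that serves smell and is silent in most tissues. Without that family its value was 0.802.

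**Figure D3:**
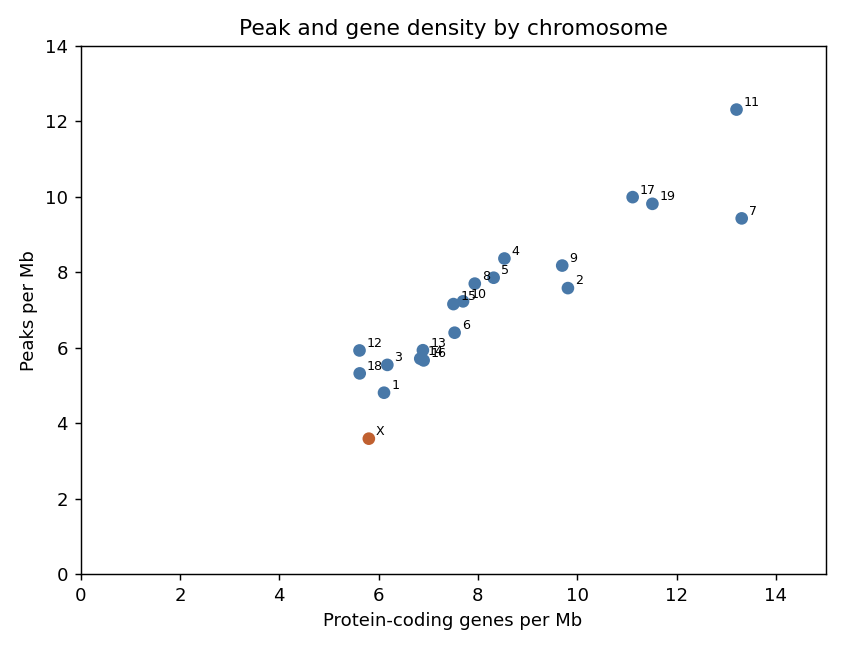
Protein-coding genes per Mb (x axis) against Zfp217 peaks per Mb (y axis), with 1 point per chromosome, X in orange; both are divided by the chromosome length taken from the last mm9 peak. The points rise together (r = 0.92), and X lies below the autosomes of similar gene density.

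Chromosome X held fewer peaks than the autosomes by each of these measures. Its density was 0.492 times that of the autosomes together (3.59 against 7.31 peaks per Mb; 95% interval of the ratio 0.453 to 0.533; exact binomial test, p = 1.3e-81), and 0.281 times among the wider 25% of peaks. Per protein-coding gene it held 0.619 peaks against 0.873, a ratio of 0.709 (0.652 to 0.769; exact binomial test, p = 2.8e-18). Both tests take peaks as independent and ignore the spread between autosomes, from 4.81 to 12.3 peaks per Mb, so their p-values are too small. Chromosomes 12 and 18, whose gene density was slightly lower than the 5.80 genes per Mb of X, held 5.93 and 5.32 peaks per Mb. Peaks on X were also narrower. Their median width was 274.5 bp (260 to 286) against 323 bp (320 to 326) on the autosomes, a difference of -48.5 bp that 100000 random sets of as many peaks never reached (permutation test, two-sided, p = 1e-05, the smallest they can give). The lowest median of any autosome was 301 bp, on chromosome 14. None of the 187 widest peaks lay on X, where 5.97 would match its share of peaks (Fisher's exact test, two-sided, adjusted p = 0.034 over 20 chromosomes). Fisher's test also takes peaks as independent, and many of the widest lay in groups elsewhere, so its p is too small. Taken as independent, 0 of 598 peaks allows a share of up to 0.615% (exact Clopper-Pearson).

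The second question was whether the peaks lay scattered or together. The median distance between neighbouring peaks was 33.8 kb, 0.374 times the mean of 90359 bp (SD 659, 100 placements) that random placement gave. Each of the 100 random placements gave a longer distance (p = 0.0099, n = 100 placements, one-sided, the smallest they can give). A total of 2214 of the 18619 neighbouring pairs (11.9%) were at most 500 bp apart, against 128 (SD 12.3) by random placement, or 17.3 times as many. Placement within 1 Mb bins keeps the number of peaks in each bin but not denser stretches inside it. It gave ratios of 0.666 for the distance and 7.61 for these pairs. The smallest distance was 52 bp. At the other end, 383 of the 2646 bins of 1 Mb (14.5%) held no peak, against 74.1 (SD 3.31) by random placement, which includes unsequenced stretches that could hold none.

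**Figure D4:**
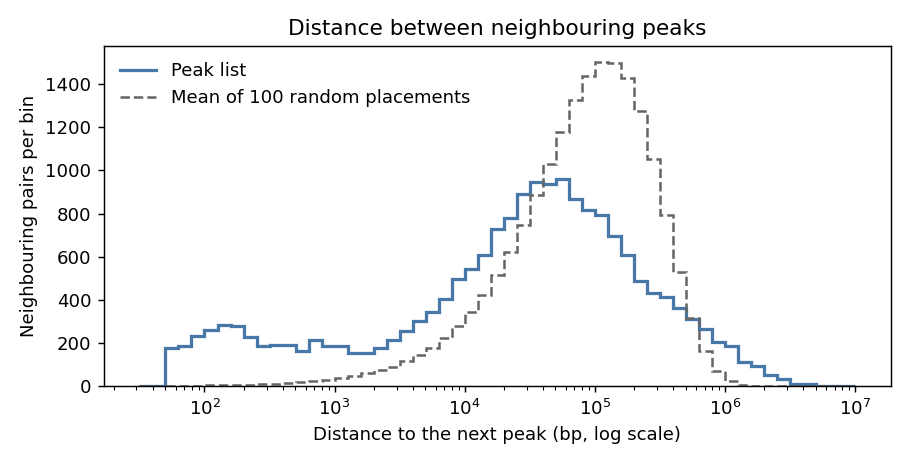
Distance from each peak to the next in bp (x axis, log scale) against the number of neighbouring pairs per bin (y axis) for the peak list (blue) and the mean of 100 random placements (dashed). The list has an excess of pairs below 10 kb, with 2214 at most 500 bp apart, and fewer pairs near 100 kb.

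Clusters of at least 3 peaks with gaps of at most 10 kb numbered 1031 and held 3976 peaks, or 21.3% of those on chromosomes 1 to 19 and X. Random placement gave 111 clusters (SD 10.1, at most 134), so the list held 9.32 times as many (p = 0.0099, n = 100 placements, one-sided, the smallest they can give). With peaks within 1000 bp of each other merged, a setting added for clusters after the data were examined, the number fell to 485 against 71.0 by random placement. Placement of the unmerged peaks within 1 Mb bins gave 495 clusters, so that the list held 2.08 times as many. The 2 settings were not combined. The ratio was 21.7 with gaps of up to 5 kb and 3.19 with gaps of up to 25 kb. Of the clusters, 648 held exactly 3 peaks and 16 held at least 10. The 3 clusters with most peaks per kb each had 3 peaks within less than 1 kb. They lay on chromosome 4 from 116961631 to 116962351, on chromosome 14 from 44245865 to 44246625 and on chromosome 1 from 75232696 to 75233472, and each became 1 peak on merging.

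The clusters with most peaks were chosen after their values were seen. The first lay at the start of chromosome 9, from 2999995 to 3038338, where 36 peaks with a median width of 827.5 bp covered 87.1% of 38.3 kb. Merged within 1000 bp, these became 1 region. Extra copies of its sequence in the cells were not tested, and without input values signal from such copies could not be told from binding. The second was on chromosome 4, from 88402688 to 88452226, with 30 peaks of median width 451.5 bp over 49.5 kb, or 15 after merging. Chromosome 6 held a cluster of 18 peaks from 47601643 to 47636329, chromosome 12 one of 17 peaks from 55809980 to 55840274, and chromosome 13 one of 16 peaks from 23622606 to 23677991. After merging, these clusters held 9, 5 and 9 peaks. On a larger scale, the 1 Mb bin with most peaks was on chromosome 7 between 52 and 53 Mb, with 93 peaks against a median of 4 per bin. Chromosome 10 held 87 peaks between 80 and 81 Mb and 69 between 79 and 80 Mb, and chromosome 8 held 73 between 73 and 74 Mb. After merging, the chromosome 7 bin held 64 peaks and the chromosome 10 bins 66 and 55.

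Some of the widest peaks lay close together and others alone. The widest of all, 5223 bp, lay on chromosome 3 from 96361463 to 96366685. The next was on chromosome 17 from 39980045 to 39984315, with 4271 bp. Chromosome 13 held the following 3 places, with peaks of 3634 bp from 21923243, 3551 bp from 21900775 and 3483 bp from 21807305. Chromosome 3 held a pair of 2993 and 2957 bp, starting at 96048913 and 96041639. Chromosome 9 held peaks of 2774 bp from 44142320 and 2758 bp from 3035581, and chromosome 13 the tenth, of 2407 bp, from 23852016. Thus 7 of the 10 widest peaks lay on chromosomes 3 and 13, which together carry 1597 of the 18737 peaks.

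Among the widest 1%, 187 peaks of at least 1009 bp, 96 lay in 14 groups of at least 3 and the others in none, among them the peaks of 4271 bp on chromosome 17 and 2774 bp on chromosome 9. Random draws of as many peaks from the list put 12.4 peaks in such groups on average and at most 32 in 1000 draws (permutation p = 0.001, the smallest they can give). Chromosome 13 held 36 of these peaks where its share of all peaks would give 7.13, or 5.05 times as many (Fisher's exact test, two-sided, adjusted p = 1.4e-14 over 20 chromosomes). Of them, 21 lay between 23622606 and 23856871 and 13 between 21807305 and 22135782, making up 75% and 72.2% of the peaks there. Chromosome 3 held 13 against 8.81, which did not pass the same exact test (adjusted p = 0.37), although 11 of its 13 lay between 96023468 and 96366685. Chromosome 9 held 18 against 10.1, which did not pass either (exact test, adjusted p = 0.10), and 13 of these lay in the cluster at its start. Another 6 lay on chromosome 12 between 55810608 and 55840274. Chromosome 2 held 4 against 13.7 (Fisher's exact test, adjusted p = 0.028). These exact tests take peaks as independent, but 96 of the 187 lay in groups, and nearly all of the 36 on chromosome 13 lay in 2. Their p-values are therefore too small.

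**Figure D5:**
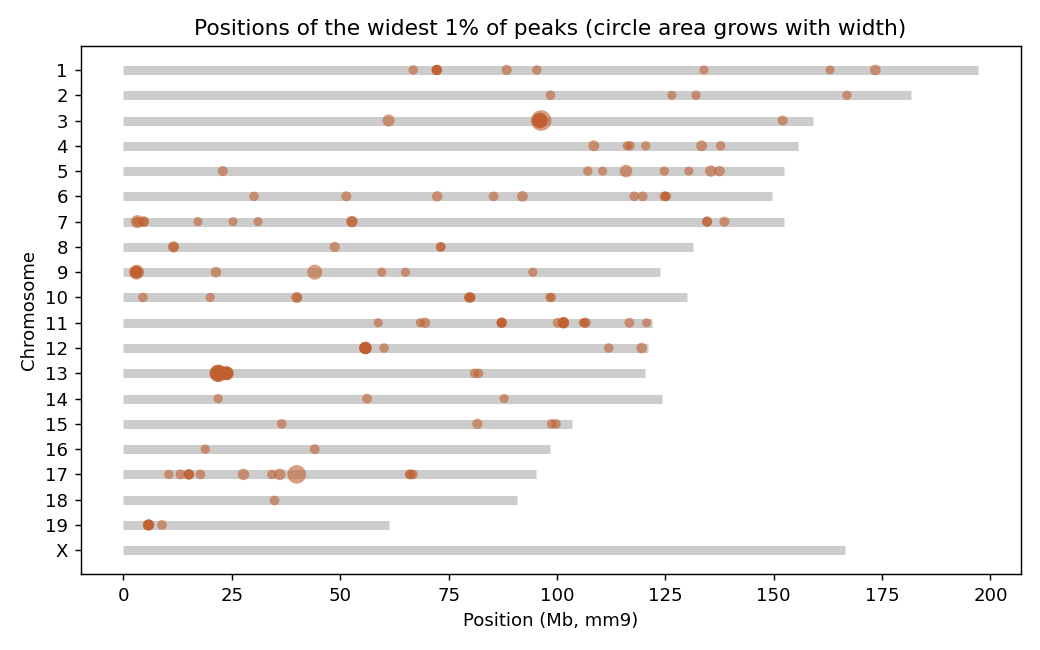
Positions in Mb (x axis, mm9) of the widest 1% of peaks on each chromosome (y axis); grey bars run to the last peak, and circle area grows with peak width. Chromosome 13 holds 36 of the 187 peaks, nearly all in 2 groups, and X holds none.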

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

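The comparisons of peak density, gene density, spacing and clusters left out 95 peaks on 9 unplaced contigs. They entered the number and width of all peaks and the ranking of the widest 1%. They are listed here because their number lies above the 3 that a count of 0 allows, a limit that any handful of peaks would pass and that does not tell binding from background. The contig Un_random held 32 of them and Y_random 26. Their median width was 282 bp. On Un_random, 18 peaks lay between 2373238 and 2472799, no more than 20 kb apart. No group held the 4 samples or more that a search for outlying samples needs, and there was no contrast between groups.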

How the results depend on the processing

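Of 40 alternative values, 31 kept their direction and side of the threshold, or stayed within the limits set for a count or median, 9 moved, and none reversed. Counted among the 31 is the gene density correlation without chromosomes 7 and 11, which kept its direction (r = 0.92) but has no p-value. The number of peaks fell from 18737 to 9370 in the wider 50% and 4697 in the wider 25%, by construction. The median width rose from 321 bp to 467 and 561 bp in these, to 387.5 bp after merging within 1000 bp, and to 328 bp without the peaks at 157 bp. The number of clusters rose from 1031 to 1612 with gaps of up to 25 kb and fell to 222 among the wider 50% and 485 after merging, which was added later for clusters, both of which leave fewer peaks; against random placement it stayed between 2.08 and 21.7 times higher. Placement within 1 Mb bins gave the 2.08 for unmerged peaks, and moved the distance ratio from 0.374 to 0.666. Merged peaks were not placed within 1 Mb bins, so the excess of clusters under both settings together was not measured. The ratio of X to the autosomes ran from 0.281 in the wider 25% to 0.709 per gene. The excess of the widest peaks on chromosomes 3 and 13 together, 3.07 times and mostly from 13, ran from 1.30 in the widest 5% to 4.62 in the widest 0.5%. Alternatives that need a score, gene positions or sequence were not run: the correlation of score with width, promoter shares, gene lists by promoter, genomic distribution, and base content and motifs. Leaving out a replicate was not possible with 1 library. The list limits all results: without depth, a missing peak cannot be told from too few reads.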

Other observations

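All tests of explanations in this part were chosen after the results were seen.

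Gene families that lie in clusters were set against the widest peaks, by chromosome only. Of 58 histone genes found by their symbols, which encode the proteins that package DNA, 48 lie on chromosome 13 and 10 on chromosome 3. Another of these genes is the direct protein-coding neighbour of 47 of those on chromosome 13 and of all 10 on chromosome 3. Chromosome 13 also carries the most tRNA genes, 105 of 408. Over 20 chromosomes, the percentage of peaks among the widest 1% had a Pearson's r of 0.91 with the number of histone genes (permutation p = 0.005, adjusted 0.012 over 5 gene families) and of 0.80 with tRNA genes (p = 0.0029, adjusted 0.012). Spearman's rho was 0.49 (p = 0.017) and 0.43 (p = 0.056), neither of which passed after adjustment (0.083 and 0.14). The values for zinc finger genes (r = 0.17, rho = 0.12), Hox cluster genes (r = -0.12, rho = -0.05) and olfactory receptor genes (r = -0.10, rho = 0.13) did not pass either, with adjusted p between 0.57 and 0.82. Without the pair of chromosomes farthest from the median number of genes, r was 0.37 for tRNA genes (p = 0.13), 0.42 for zinc finger genes (p = 0.068), -0.19 for Hox cluster genes (p = 0.26) and 0.11 for olfactory receptor genes (p = 0.67), by permutation. Without chromosomes 13 and 3, none of the 58 histone genes found by symbol is left, so that relation rests on them. Histone genes under other symbols were not counted.

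A candidate explanation for the widest peaks is that those on chromosomes 3 and 13 mark histone gene clusters (r = 0.91), and tRNA genes may account for them as well (r = 0.80). Neither is settled, since both relations lean on chromosome 13, whose wide peaks prompted them, and the tRNA relation did not pass without chromosomes 13 and 6 (permutation p = 0.13). Chromosome 3 alone, with 13 of the widest against 8.81, did not pass its exact test (adjusted p = 0.37). Among 50 consecutive peaks, up to 28 of the 36 widest lay together on chromosome 13 and 11 of the 13 on chromosome 3. Random order of each chromosome's peaks gave at most 13 and 8 (permutation test, one-sided, adjusted p = 6.7e-05 each), and 6 of 20 chromosomes passed. This scan restates groups already seen in the same peaks, so it cannot decide whether wider peaks along the whole chromosomes were their source. The median width was 334 bp (317 to 355) on chromosome 13 and 305 bp (289 to 321) on chromosome 3. The other chromosomes had a median of 321 bp (317 to 324). These medians showed no clear widening of the typical peak on either chromosome. Extra copies of a sequence in the cells were not tested, either here or for the widest peaks on chromosomes 9 and 17.

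The number of genes alone predicted a higher density on X than was found, but this does not settle whether few genes are the whole cause. Its 3.59 peaks per Mb lay below the 95% prediction interval from the line through the 19 autosomes (3.77 to 7.08), and below that without olfactory receptor genes (4.11 to 6.61). The margin was small with all genes, where the Poisson interval of X (3.31 to 3.89) reached into the predicted one. Only 6 of the olfactory receptor genes lie on X, so leaving them out changes mainly the autosomes. Which genes are active in these cells was not measured. A single X copy per cell could lower the signal there, and the narrower peaks (a median difference of -48.5 bp) are consistent with that. Weaker or rarer Zfp217 binding on X would give the same picture and stays open. The labels do not give the karyotype of the line, and a known number of X copies would not by itself exclude weaker binding. The list held 2 peaks on chromosome Y and 26 on Y_random, but without read depth these do not settle the number of X copies.

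Peaks within 500 bp of each other were 7.61 times as frequent as in placement within 1 Mb bins. Differences in density between 1 Mb bins alone are therefore argued against as the cause. Denser stretches shorter than 1 Mb were not tested, since that placement spreads their peaks over the whole bin. Pairs from 50 to under 100 bp apart were 7.60 times as frequent as pairs from 450 to under 500 bp apart (593 against 78), with a steady fall between. This is consistent with one enriched region being reported as several peaks. Separate binding sites side by side were not tested, since the signal between the peaks is unknown.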
